A study of Mus musculus with 50 samples.

How the data were processed

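GeoMx digital spatial profiling captures barcodes of RNA probes from chosen regions of a stained section. Per the labels' protocols, paraffin sections of perfused mouse lungs were stained for CD45, CD68 and DNA, and libraries were made with the mouse whole transcriptome probe kit. How regions were called injured, peri-injured or healthy is not given in the sources used here. CD45 and CD68 set the segments and are no finding between them. Each of the 4 sections carries 1 study identifier, taken as 1 animal. Both wild type sections were collected on 1 plate and both mutant sections on another, per the file headers, so genotype and plate cannot be told apart. All libraries were sequenced in 1 run. The treatment label of the air samples names ozone exposure while their titles and time point say air, and the titles were followed. The design text gives no genotype for the old section, and the sample labels give mutant.

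The deposited values are counts of probe barcodes after removal of duplicate reads by their molecular identifiers, per the file headers, which name the GeoMx NGS Pipeline, version 2.3.4. Barcodes with no count are not listed and were set to 0. The files hold 20238 identifiers, of which 20175 form 1 continuous range of numbers and were analysed. The other 63 lie outside it and stayed out of library sizes. None of the identifiers matched a name in the reference tables, so the lists of lung cell type and pathway genes fixed beforehand were not evaluated. The deposited worksheets give an area per segment with no unit printed. The share of reads beyond the first per molecule was 79.8% to 95.3%.

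Section was the unit of replication. Counts were summed per section and segment (8 sums), or per section and region type within a segment (6 sums), or both (12 sums). Identifiers were kept by filterByExpr with its minimum count of 10, scaled with TMM, and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided, Benjamini-Hochberg, adjusted p under 0.05) with the section as a block, in R 4.3.3. For the interaction of region type and segment (12 sums) the block was the section within a segment type. The SE of a log2 fold change was its size over the square root of F. Comparisons of 1 section with 1 section used log2 CPM with a prior count of 2, and the rule of a difference of at least 1 with no overlap of regions. CPM levels are on TMM-scaled library sizes of all 48 segments, with the SD between regions of 1 section, which share an animal. P-values over regions are too small for statements on animals. They are given for the exact permutation tests, which shuffled region types within sections. They also underlie the counts with regions as libraries, with voom and in single sections.

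Both segments of a region come from the same animal and region, so the region numbers pair them. The section block holds that pairing in the comparison of segments. The block of the interaction does not, so it treats the injury differences of both segment types as independent. Deviations from group means in both segments of a region had a median correlation of 0.0455 over 1459 abundant identifiers, against -0.0139 for other regions of the group, and 15 of 24 segments correlated best with their own region. No 2 regions of a group had counts within sampling noise of each other, with at least 1.13 as chi-square per degree of freedom over 60 pairs.

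Lists from the air section took identifiers with a paired difference of 1 sign in all 4 regions, up to 200. Of 248 identifiers kept there, 59 met this in each direction. They were tested with camera in limma 3.58.1 against the other kept identifiers. Chance alone can give 1 sign in 4 regions, and how much of each list it accounts for was not estimated. Named identifiers were at most 2 higher and 2 lower per comparison, with the largest change among those that passed, the same direction in every section and a mean level above the median. This rule, the tests and most alternatives were fixed before the data were examined. Alternatives were upper quartile factors, DESeq2 1.42.0, voom with a section correlation, 2 other filters (none, and 50 CPM), a prior count of 10, regions as libraries, single sections, and leaving out each section, each region or the segments under 50000 counts. These were 15 of 24 CD68+ and 3 of 24 CD45- segments. Regions as libraries and voom were first run with the filter taken on regions, which kept 1451 identifiers in CD45- and 336 in CD68+ segments for injury. They were then run on the identifiers of the sums, so that 1 choice changed at a time, after the first values had been seen, and both versions are reported. The background of the lists was set to the identifiers kept in air before the list results were computed. The exact permutations of named identifiers and of list scores (mean log2 CPM of the list less that of the other identifiers), the refits without RTS0076055, and the refits without identifiers counted mostly in 1 segment were added after seeing the data. The last were defined over all 48 segments without regard to groups, as a highest CPM at least 5 times the next one from at least 20 counts.

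The tests were run on simulated counts with 200 changed identifiers each. Of 100 changed 2-fold, 49 were recovered for the comparison of segments, 35 and 50 for injury in CD45- and CD68+ segments, and 9 for the interaction. Of 100 changed 8-fold, 100, 100, 100 and 90 were recovered, with 5, 6, 9 and 2 false calls. The size rule recovered 22 and 99 of 100 for ozone against air in CD45- segments, with 5 false calls. The list test called 1 of 100 simulated lists with no shift and 100 of 100 with a shift of 0.5. The real macrophage-enriched list differed from the others by 0.166 in CD45- segments, less than that shift. Each identifier was simulated with the dispersion of the trend at its level, without a spread of its own. Other groupings of the real regions within sections gave a median of 23 injury calls in CD45- and 6 in CD68+ segments. Without identifiers counted mostly in 1 segment these medians were 11 and 3. The simulated false calls therefore cannot be carried over to the real counts. Simulated counts had no outlying single segments, and identifiers were drawn independently. False calls of the list test at the estimated correlation of 0.107 in the real list are therefore not known.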

Results

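Whole-transcriptome probe counts were collected from 4 lung sections, 1 for each condition. The sections came from a young wild type mouse in filtered air, a young wild type mouse after ozone, a young mouse with mutant surfactant protein C (SP-C) after ozone, and an old mutant mouse after ozone. Surfactant protein C is made by alveolar type 2 cells. Young mice were 12 weeks and the old mouse 80 weeks of age, and exposed lungs were taken 72 hours after 3 hours at 0.8 ppm ozone. In 24 regions the CD68+ macrophage segment and the CD45- non-immune segment were captured separately, which gave 48 segments. The air section had 4 regions described as healthy. The wild type ozone section had 4 injured and 4 peri-injured regions, and each mutant section had 3 of each.

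CD68+ segments held 20043 to 101968 counts, with a mean of 48278 ± 19582 (SD, n = 24). CD45- segments held 32705 to 300708 counts, with a mean of 118516 ± 63324 (SD, n = 24). An identifier at 50 CPM (counts scaled to 1e6 per segment) therefore rests on few counts in most CD68+ segments. The probe identifiers (RTS numbers) could not be paired with gene names, so identifiers are given as listed and no gene or pathway is named. The 2 no template controls held 4 and 229 counts.

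The first comparison asked which transcripts mark the macrophage segments. RTS0081106 was 11.8-fold and RTS0064055 10.9-fold higher in CD68+ than in CD45- segments, each in all 4 sections. In injured regions of the wild type ozone section, RTS0064055 stood at 2595 ± 1065 CPM in CD68+ and 109 ± 42.8 CPM in CD45- segments (SD, n = 4). In the air section its levels were 283 ± 82.5 and 19.2 ± 25.7 CPM (SD, n = 4), the latter from 4 counts. The log2 fold changes were 3.56 (SE 0.28, edgeR adjusted p = 5.59e-10) for RTS0081106 and 3.44 (SE 0.28, edgeR adjusted p = 5.59e-10) for RTS0064055. RTS0067301 was lower in CD68+ segments of all 4 sections, with a log2 fold change of -1.57 (SE 0.29, edgeR adjusted p = 0.000922) and at most 4 counts in any CD68+ segment. RTS0067237 was also called lower, at -1.49 (SE 0.32, edgeR adjusted p = 0.00406), with 189 of its counts in the CD45- segment of peri-injured region 7 of the wild type ozone section. Without that region its log2 fold change was -0.20 (edgeR adjusted p = 0.883, where all alternatives gave 0.000661 to 0.883).

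Of 14591 identifiers tested on 8 sums, 274 were higher and 161 lower in CD68+ segments at an edgeR adjusted p under 0.05. The median size of these differences was 1.04 on the log2 scale, and 237 of the higher and 145 of the lower identifiers had the same direction in all 4 sections. DESeq2 called 137 identifiers, all of them among the 435, and 138 passed without the wild type ozone section. With each region as a library, 930 passed with the section as a block and 847 with the region as a block, which keeps the pairing of both segments of a region. Most were then lower in CD68+ segments (684 and 618), so the balance of directions turned. Both of these fits take regions of the same animal as replicates. Without the wild type ozone section RTS0064055 had 2.78.

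Injured and peri-injured regions of the same sections were compared to find what distinguishes injured tissue after ozone. In CD68+ segments RTS0076055 was 46.7-fold and RTS0064947 13.6-fold higher in injured regions, and in all 10 injured regions both exceeded every peri-injured region of the same section. RTS0076055 had means of 39.5 ± 48.6 CPM in peri-injured and 771 ± 1001 CPM in injured regions of the wild type section (SD, n = 4). In the young mutant section these were 699 ± 609 and 102110 ± 57556 CPM, and in the old mutant section 489 ± 268 and 11830 ± 7733 CPM (SD, n = 3). It took up to 15.9% of all counts in a young mutant injured segment. Over the young mutant injured segments the 10 most abundant identifiers held 15.0 ± 4.24% (SD, n = 3), from 12.05% to 19.89%. The air regions, as the unexposed background, held 169 ± 130 CPM (SD, n = 4). RTS0064947 had means of 81.6 ± 77.5 and 2694 ± 986 CPM in the young mutant section and 63.3 ± 56.9 and 496 ± 273 CPM in the old mutant section (SD, n = 3). In the wild type section it had 17.3 ± 20.3 and 60.8 ± 22.9 CPM (SD, n = 4), from at most 5 counts per region.

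**Figure D1:**
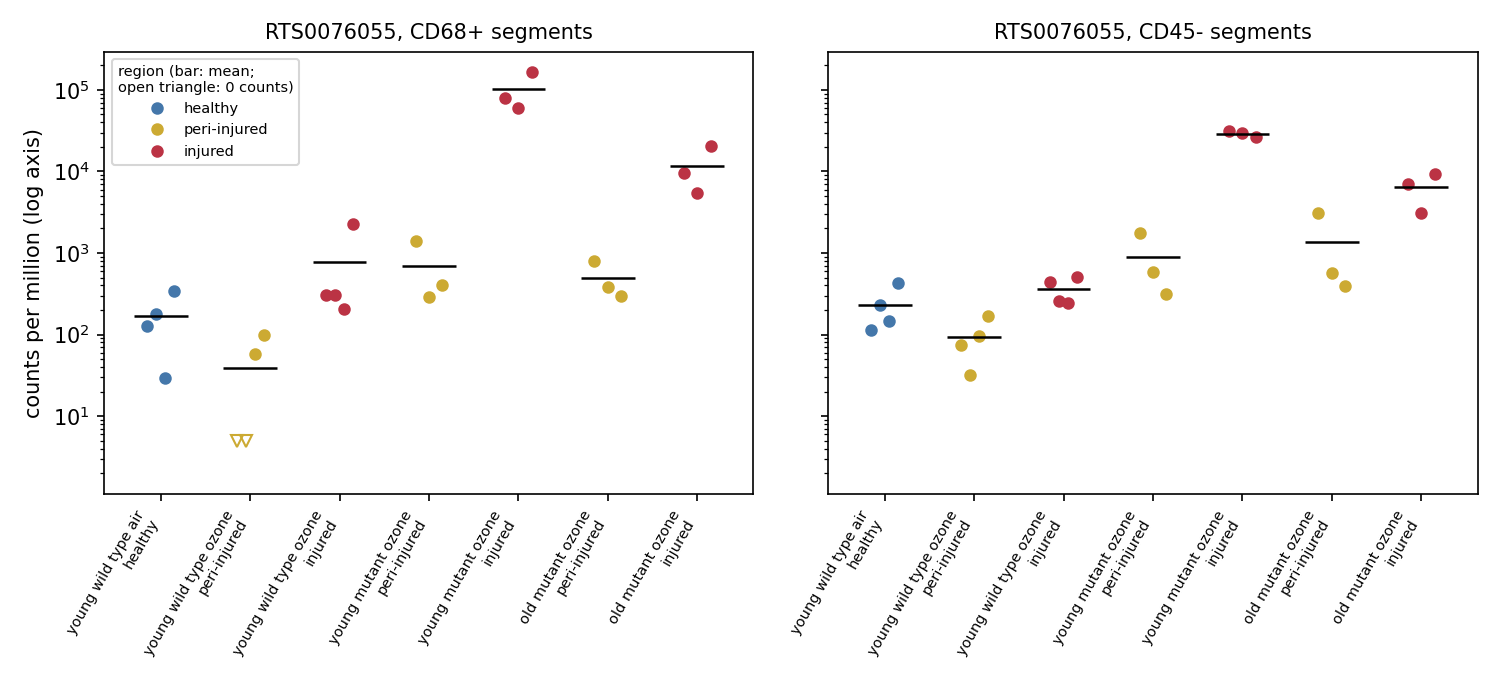
CPM (log axis) of RTS0076055 in every captured region, CD68+ segments on the left and CD45- segments on the right. Each point is a region, bars are group means, and open triangles mark the 2 wild type ozone peri-injured CD68+ regions with 0 counts, drawn at an arbitrary low height; young mutant injured CD68+ segments averaged 102110 CPM.

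The log2 fold change over the 3 sections was 5.55 (SE 0.32, edgeR adjusted p = 1.10e-13) for RTS0076055 and 3.77 (SE 0.35, edgeR adjusted p = 1.04e-08) for RTS0064947. Without the young mutant section these were 4.44 and 2.66, and without the old mutant section RTS0076055 had 6.26. RTS0068460 had -1.53 (SE 0.25, edgeR adjusted p = 0.000593), and RTS0065530 had -2.28 (SE 0.48, edgeR adjusted p = 0.0152). RTS0065530 had 255 of its counts in peri-injured region 11 of the old mutant section, without which its log2 fold change was -0.12 (edgeR adjusted p = 0.974, where alternatives gave 5.97e-08 to 1). Without the old mutant section RTS0068460 had -0.91 (edgeR adjusted p = 0.994, where alternatives gave 3.96e-17 to 1). A two-sided exact permutation of region types within sections gave p = 7.14e-05 for RTS0076055 and for RTS0064947, the smallest value the 28000 arrangements can give, p = 0.205 for RTS0068460 and p = 0.351 for RTS0065530. These identifiers were picked on the same regions, so the permutation is no independent evidence.

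Of the 3176 identifiers tested in CD68+ segments, 9 were higher and 8 lower in injured regions at an edgeR adjusted p under 0.05. Among the 8, RTS0076369, RTS0076370 and RTS0076763 were also among the 10 most macrophage-enriched identifiers of the air section, and were singled out after their values were seen. DESeq2 called 3 identifiers, and voom with a section correlation called 0, where 277 had an unadjusted p under 0.05 (227 in edgeR, 22 in DESeq2). The count was 4 without the old mutant section and 1 without peri-injured region 4 of the young mutant section.

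In CD45- segments RTS0076055 was 9.06-fold higher in injured regions, and 9 of 10 injured regions exceeded all peri-injured regions of their section. It had means of 92.8 ± 57.8 CPM in peri-injured and 361 ± 134 CPM in injured regions of the wild type section (SD, n = 4). In the young mutant section these were 889 ± 776 and 29026 ± 2511 CPM, and in the old mutant section 1364 ± 1533 and 6536 ± 3201 CPM (SD, n = 3). The air regions held 228 ± 141 CPM (SD, n = 4). Its log2 fold change was 3.18 (SE 0.26, edgeR adjusted p = 9.83e-10), and it did not pass with DESeq2 (2.99) or voom (2.93). Without the young mutant section it was 2.18, and without peri-injured region 7 of the old mutant section 3.78. RTS0080379 was lower at -2.14 (SE 0.30, edgeR adjusted p = 0.000102), with 103 of its counts in peri-injured region 4 of the young mutant section, without which it had -0.97 (edgeR adjusted p = 0.570, where alternatives gave 2.48e-12 to 1.00). RTS0079559 was called higher at 3.01 (SE 0.41, edgeR adjusted p = 3.82e-05), with 127 of its counts in injured region 2 of the young mutant section, and without that section it had 1.01 (edgeR adjusted p = 0.995, where alternatives gave 4.25e-16 to 1.00). RTS0081423 was called lower at -3.01 (SE 0.44, edgeR adjusted p = 0.000167), with 523 of its counts in peri-injured region 7 of the wild type section, without which it had -0.17 (edgeR adjusted p = 0.983, where alternatives gave 1.28e-49 to 1.00). The exact permutation gave p = 0.000143 for RTS0076055, p = 0.00314 for RTS0080379, p = 0.03 for RTS0079559 and p = 0.215 for RTS0081423.

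Of the 16703 identifiers tested in CD45- segments, 34 were higher and 24 lower in injured regions at an edgeR adjusted p under 0.05, and with upper quartile factors 15 were higher and 5 lower. DESeq2 called 1 identifier, and voom with a section correlation called 0, where 1076 had an unadjusted p under 0.05 (1037 in edgeR, 61 in DESeq2). The count was 18 without peri-injured region 4 of the young mutant section and 164 without the wild type section.

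Of the 3175 identifiers tested in both segment types, 5 were higher and 2 lower in injured regions in both. The 5 were RTS0076055, RTS0064947, RTS0075359, RTS0064300 and RTS0068724, and the 2 were RTS0068460 and RTS0068462. Those outside the rule for named identifiers are listed after their values were seen. The count of 7 fell to 4 with upper quartile factors, to 0 with DESeq2 and voom, to 2 without the old mutant section and to 1 without peri-injured region 4 of the young mutant section, and was 14 without the wild type section. Over 37 alternatives RTS0076055 was shared in 33, RTS0064947 and RTS0064300 in 30 each, RTS0075359 in 16, RTS0068462 in 15, RTS0068460 in 11 and RTS0068724 in 6.

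**Figure D2:**
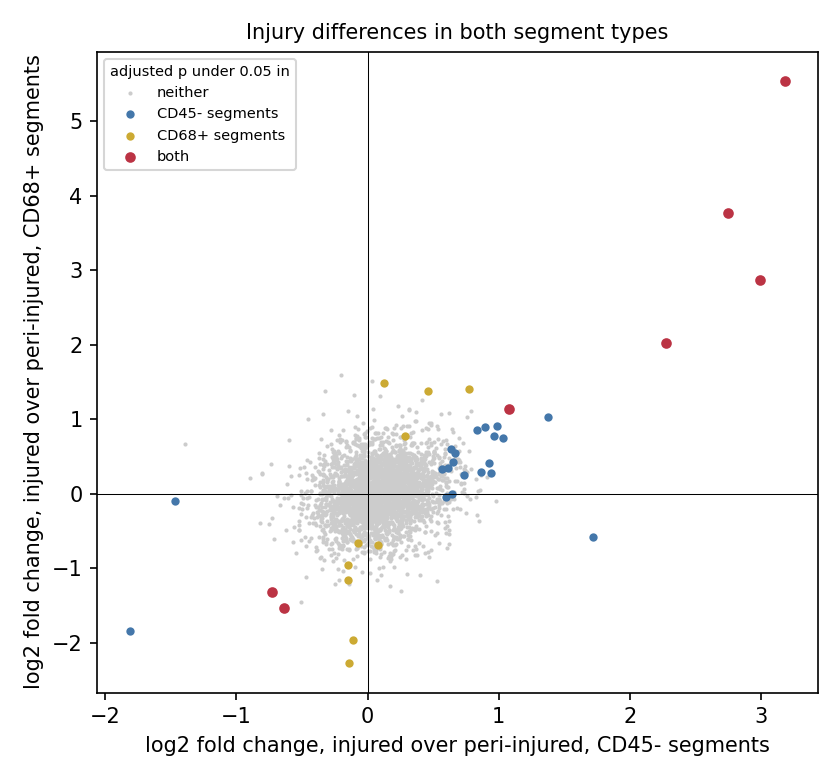
Log2 fold change of injured over peri-injured regions in CD45- segments (horizontal axis) and CD68+ segments (vertical axis) for the 3175 identifiers tested in both. Colours mark an edgeR adjusted p under 0.05 in neither segment type, in CD45-, in CD68+ or in both; 5 identifiers passed upward and 2 downward in both.

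Whether the injury difference itself differed between segment types was tested as an interaction over 12 sums. RTS0076055 rose more in CD68+ segments, with a log2 difference of 2.54 (SE 0.51, edgeR adjusted p = 0.032) and the same direction in all 3 sections. The call was marginal, since it passed in only 7 of 20 repeats that each left out a region, with differences of 2.24 to 2.73. RTS0075079 had a difference of 3.27 (SE 0.64, edgeR adjusted p = 0.0224) and passed in 11 of these 20, with 2.45 without peri-injured region 5 of the young mutant section and 2.69 without that section. RTS0070823 had -4.30 (SE 0.55, edgeR adjusted p = 2.87e-05) and RTS0068006 had -3.76 (SE 0.56, edgeR adjusted p = 0.000403). They had 241 and 173 of their counts in the CD68+ segment of peri-injured region 7 of the wild type section, without which they had -1.53 and -0.57 and neither passed. In all, 4 of 9319 identifiers had a higher and 2 a lower injury difference in CD68+ segments. The others of the 4 were RTS0074748 (3.77, edgeR adjusted p = 0.00169) and RTS0066914 (2.75, edgeR adjusted p = 0.0484), named after their values were seen. RTS0074748 had 314 of its counts in the CD68+ segment of injured region 2 of the wild type section, and did not have the same direction in all 3 sections. DESeq2 called 0, where 65 had an unadjusted p under 0.05 (427 in edgeR).

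The air section gave lists of 59 identifiers higher and 59 lower in CD68+ than CD45- segments in all 4 air regions. In CD68+ segments the list of non-immune identifiers had a median log2 fold change of -0.13 in injured regions, against 0.09 for the other identifiers (camera p = 0.00227, but 0.116 with an estimated correlation, and two-sided exact permutation of regions within sections p = 0.00207). In CD45- segments the macrophage-enriched list had a median of 0.26, against 0.10 for the others (camera p = 0.00369, but 0.279 with an estimated correlation and exact permutation p = 0.479). The permutation was chosen after the camera values were seen. Over 8 alternatives that set the list against the others, p ran from 0.00141 to 0.116 for the non-immune list and from 1.19e-22 to 0.703 for the macrophage-enriched list, highest without the wild type section.

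The share of captured area in the CD68+ segment was 38.1 ± 14.8% in air regions (SD, n = 4) and 27.6 ± 7.25% in wild type ozone regions (SD, n = 8). It was 11.1 ± 5.05% in young mutant and 26.3 ± 13.2% in old mutant regions (SD, n = 6). Between injured and peri-injured regions the share differed by -4.62 percentage points (exact permutation within sections, two-sided, p = 0.288, 0.431 adjusted over 3 measures). It was higher in injured regions in 1 of 3 sections. The CD45- segment area differed by 7080 area units (exact permutation p = 0.0819, adjusted 0.246), higher in injured regions in 2 of 3 sections. The CD68+ segment area differed by 186 area units (exact permutation p = 0.862, adjusted 0.862). None of the 3 measures passed, and without the young mutant section the CD45- area difference was 10720 area units (exact permutation p = 0.0186, unadjusted, where alternatives gave 0.0186 to 0.337).

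**Figure D3:**
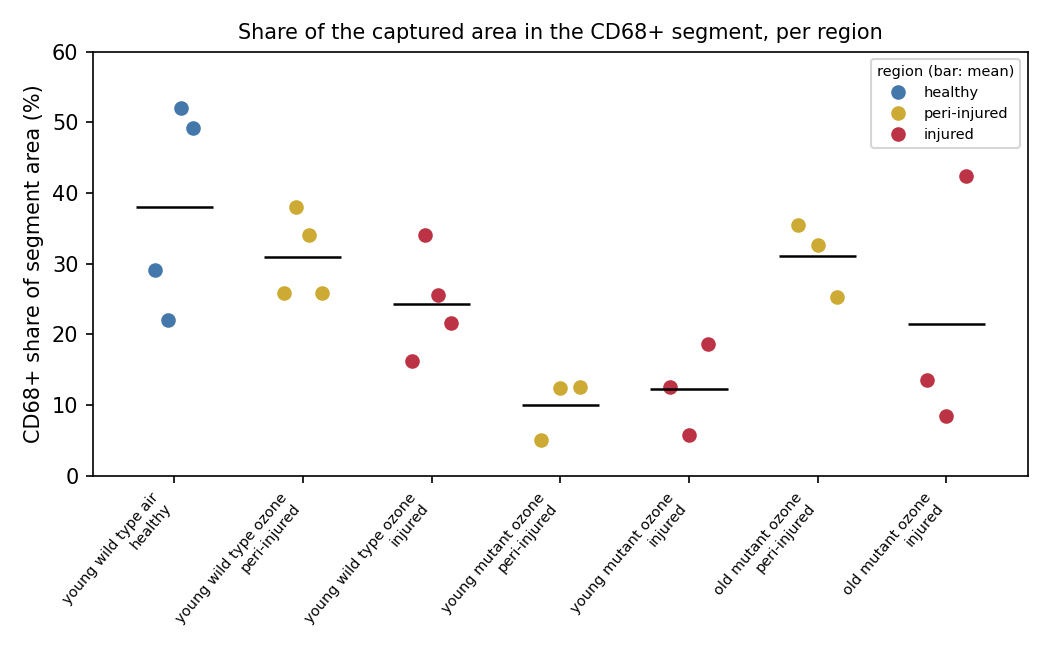
Percentage of captured area that fell in the CD68+ segment, per region (points) with group means (bars). The young mutant regions averaged 11.1% and the air regions 38.1%.

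The remaining comparisons set 1 section against 1 section, so regions describe the sections and no test across animals was possible. An identifier was counted where the mean log2 CPM differed by at least 1 and the regions of both sections did not overlap. The share without overlap is set beside that for regions assigned to the sections at random. Regions of 1 section share an animal, so any pair of animals can exceed the random share. For ozone against air in young wild type mice, RTS0081477 was 13.8-fold higher after ozone in CD68+ segments. It held 2197 ± 1135 CPM in injured, 829 ± 147 CPM in peri-injured and 56.8 ± 54.3 CPM in air regions (SD, n = 4), the last from 11 counts. Its log2 difference was 3.78, and 2.46 with a prior count of 10. RTS0066938 was 4.36-fold higher, at 3774 ± 1126, 3486 ± 339 and 612 ± 49.7 CPM (SD, n = 4), while RTS0068472 and RTS0076368 were 2.63-fold and 2.48-fold lower. In these segments 19 of 477 identifiers were higher and 8 lower, and 9.85% of identifiers did not overlap, where random assignment of regions gives 0.404%. Without region 11 of the air section the count was 47, and 43 without region 10.

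In CD45- segments, RTS0081052 was 12.0-fold and RTS0068724 9.33-fold higher after ozone, and RTS0061870 and RTS0069143 were 2.94-fold and 2.89-fold lower. RTS0081052 held 465 ± 77.0 CPM in injured, 417 ± 113 CPM in peri-injured and 23.5 ± 36.1 CPM in air regions (SD, n = 4). The air values of RTS0081052 and of RTS0068724 rest on 5 counts each, and their log2 differences of 3.58 and 3.22 became 2.10 and 1.99 with a prior count of 10. Without air region 10 RTS0081052 had 4.23. Of 1819 identifiers 43 were higher and 22 lower, and 7.04% did not overlap, where random assignment of regions gives 0.404%. The air CD45- segments held 43142 ± 9803 counts (SD, n = 4), against 151496 ± 65444 (SD, n = 8) after ozone. The effect of this depth gap was not tested, and leaving out segments under 50000 counts was not tried here. With upper quartile factors 51 were higher and 14 lower. Without air region 8, 10, 11 or 12 the counts were 117, 132, 112 and 107.

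Mutant and wild type mice were compared after ozone at 12 weeks, with genotype and collection plate changing together. RTS0081029 was 41.0-fold higher in mutant CD45- segments, with 1430 ± 368 CPM in injured and 1011 ± 62.6 CPM in peri-injured regions (SD, n = 3). The wild type ozone regions held 20.4 ± 10.1 and 17.9 ± 18.1 CPM (SD, n = 4), at most 4 counts per region. Its log2 difference was 5.36, and 3.86 with a prior count of 10. RTS0063348 was 6.53-fold higher in CD45- and 9.82-fold higher in CD68+ segments, and RTS0064439 and RTS0066800 were 5.73-fold and 5.49-fold lower in CD45- segments. In CD68+ segments RTS0076158 was 5.44-fold higher, RTS0081477 7.68-fold lower and RTS0070870 3.87-fold lower. In all, 18 of 2502 identifiers were higher and 28 lower in CD45- segments, and 7 of 392 higher and 10 lower in CD68+ segments. Of all identifiers, 3.20% and 6.12% did not overlap, where random assignment of regions gives 0.0666%.

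Old and young mutant mice after ozone were captured on 1 plate. RTS0070891 was 2.09-fold higher in old CD45- segments, the only 1 of 1356 identifiers counted, but its log2 difference of 1.06 fell to 0.73 with a prior count of 10, where 0 were counted, and to 0.98 without old mutant region 9. In CD68+ segments 3 of 287 were lower in the old mouse, RTS0081106 (2.98-fold), RTS0066938 (2.12-fold) and RTS0070408 (2.02-fold), the last named after its value was seen. Regions did not overlap for 1.40% and 2.44% of identifiers, where random assignment of regions gives 0.216%. With a prior count of 10 the CD68+ count was 1, and without young mutant region 2 RTS0066938 had -0.93. Leaving out 1 region gave counts of 1 to 4 in CD45- and 2 to 6 in CD68+ segments, the highest without old mutant region 9 and without young mutant region 5.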

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

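Tests chosen only after results were seen were those without RTS0076055, those on identifiers counted mostly in 1 segment or region, that of the collection plate, and that of identifiers shared by both segment types; regroupings by the smallest p were added after those by count.

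The comparison of CD68+ with CD45- segments stood clear of chance: of 100 swaps of segments within regions only 1, the real one, gave as many as 435 identifiers, and the highest other gave 81. For injury, chance was not excluded for the counts. In CD45- segments 14 of 100 regroupings of regions within sections gave at least 58 identifiers, with 114 as the highest other. In CD68+ segments 6 of 100 gave at least 17, with 21 as the highest other. A p as small as the smallest real one appeared in 12 of 100 regroupings in CD45- segments (real 5.88e-14, smallest other 3.16e-20) and in 19 of 100 in CD68+ segments (real 3.48e-17, smallest other 8.16e-86), so chance was not excluded there either.

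The injury difference itself differed between segment types for 6 identifiers by the interaction test, and 27 of 100 regroupings gave at least as many, with 13 as the highest other, so chance was not excluded. Of the 6, 4 were identifiers counted mostly in 1 segment, for RTS0066914 a segment of the air section. For the 7 identifiers called in the same direction in both segment types, 100 regroupings kept both segments of a region together. Only 1, the real one, gave as many (highest other 4), which covers the edgeR count over all regions. The test was chosen after the 7 had been seen, so alone it does not exclude chance. Other versions were not regrouped, and shared 0 identifiers with DESeq2 or voom and 1 to 8 without 1 region. All 8 falls in CD68+ segments were still called lower with RTS0076055 left out of the counts. TMM scaling offsets the share of a single identifier whether or not it is left out. The refit could therefore hardly have come out otherwise, and it does not decide whether that share plays a part.

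Identifiers counted mostly in 1 segment were 143 of 20175, spread over 45 of the 48 segments, and made up 0.683% of identifiers tested for injury in CD45- segments but 41.4% of those called. RNA of a structure that spans the region would raise the other segment too, and among 182 cases at least 5 times above the next segment of the same type, chosen without regard to the other segment, that segment was raised at least 2 times in 16.5%, against 15.2% in the other regions, which argues against that source for most of them. A structure confined to 1 segment type and a fault of 1 probe in 1 library stay open and were not tested apart, as does a biological source. With these identifiers left out, CD68+ segments gave 20 injury calls, and only 1 of 100 regroupings, the real one, gave as many (highest other 16). Leaving them out was chosen after the data were seen. With them kept, 6 of 100 gave at least the real count, so chance is not excluded. In CD45- segments 37 passed and 12 of 100 gave as many (highest other 92), so chance was not excluded.

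The 5 identifiers that rose in injured regions in both segment types may reflect macrophage RNA in the CD45- segments, in which case their ratio of CD45- to CD68+ CPM would not exceed that of macrophage-enriched identifiers. Of the 5, 0 lay above the highest of 10 such ratios in all 3 ozone sections, although RTS0064300 did in the old mutant section (1.33 against 0.784) and RTS0068724 in the wild type section (1.14 against 0.896). The bound was lenient in the young mutant section, where the highest of the 10 was 3.91. Against the medians of the 10 in the wild type, young mutant and old mutant sections (0.725, 0.650 and 0.483), RTS0064300 lay above in all 3 (0.877, 1.48 and 1.33) and RTS0075359 below in all 3 (0.630, 0.338 and 0.385), while RTS0076055 (0.429, 0.218 and 0.530) and RTS0064947 (0.383, 0.320 and 0.725) lay above in the old mutant section only, and RTS0068724 (1.14, 0.349 and 0.714) below in the young mutant section only. The 10 differed widely. In the same order of sections RTS0081106 had 0.0376, 0.0479 and 0.252, RTS0064820 0.0514, 0.109 and 0.144, and RTS0064807 0.103, 0.143 and 0.268. All 5 lay above these in every section (lowest 0.383, 0.218 and 0.385). Macrophage RNA carried over at the rate of these identifiers would not account for the ratios of the 5. The answer thus depends on the reference, and the ratios do not decide. A rise in the non-immune cells themselves stays open and was not tested apart.

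RTS0081029 was the only 1 of 20175 identifiers with every mutant segment over 5 times every wild type segment, at 693 or more per 1e6 unscaled counts in 24 mutant and 52.9 or less in 24 wild type segments, and 0 showed the opposite. The collection plate could be a source, and the no template control of the mutant plate held 0 counts of RTS0081029 but only 4 counts in all, so plate and genotype cannot be told apart. A difference with genotype or strain is the biological hypothesis, which the design does not separate from the plate.

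Groups of 4 regions, all from wild type sections, were screened for a region far from the others. It was found in 18 of 213 sets of values, where chance gives about 10.7 for values not picked beforehand. The screened identifiers were the named ones, and some owed their call to the region that was then flagged. The excess is therefore partly built in. Mutant groups had 3 regions and were not screened. In peri-injured region 7 of the wild type ozone section, CPM stood high at 5514 for RTS0081423 and 1992 for RTS0067237 in the CD45- segment. In its CD68+ segment CPM stood high at 4683 for RTS0070823, 3362 for RTS0068006 and 38.9 for RTS0081029. In injured CD68+ segments of that section RTS0076055 stood high in region 9 at 2271 CPM (others 271 ± 58.1) and RTS0067301 in region 2 at 18.1 CPM, while RTS0081477 was low in region 9 at 505 CPM and RTS0065530 in region 3 at 0 CPM. In its peri-injured region 5 the CD68+ segment stood high at 259 CPM for RTS0063348 and 3994 CPM for RTS0076368. In air CD45- segments RTS0064439 was low in region 8 at 135 CPM, and RTS0081029 was high in region 8 at 45.1 CPM, RTS0070870 in region 10 at 1997 CPM and RTS0070823 in region 11 at 109 CPM. In air CD68+ segments RTS0064947 was high in region 10 at 88.97 CPM and RTS0081052 in region 8 at 732 CPM. The CD45- segment of injured region 2 of the wild type ozone section had the high total of 300708 counts. For RTS0067301 and RTS0081029 the other regions of the flagged groups held 0 CPM. No wild type segment held over 4 counts of RTS0081029.

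Identifiers outside the analysed range held 308 counts over the 48 segments, 0.00769% of all, with 0.0115% on the mutant plate and 0.00393% on the wild type plate. The no template controls held 0 such counts of 233, which allows up to 1.29%.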

How the results depend on the processing

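Alternatives chosen only after seeing the data left out RTS0076055 or identifiers counted mostly in 1 segment, took all tested identifiers as the background of a list, or permuted list scores. Regions as libraries and voom were first run with the filter on regions, and the versions on the identifiers of the sums were chosen after those values were seen. The cause of a change was not tested unless it is named. Of 884 values of 35 named results under an alternative, 779 kept their call or size, 95 lost the call, 10 moved and 0 changed sign. In comparisons of 1 section with 1 section, a size was kept if it shifted by less than the pooled SD of regions. Whether the size rule was still met was not checked there, so a value under the limit of 1 can be among the 779. Identifiers of the tested comparisons had been picked for the same direction in every section, so a change of sign was unlikely beforehand. Repeats that filtered an identifier out, or gave it no adjusted p in a tested comparison, are not among the 884. Lost calls can therefore be undercounted. Counts under alternatives not given here changed by at most 1.5 times.

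For CD68+ against CD45- segments (435 identifiers), DESeq2 gave 137, segments of at least 50000 counts 156, regions as libraries 930 with the section alone and no replicate block and 847 with the region as replicate block, and 229 with the filter on regions (491 identifiers tested). Leaving out 1 section or region gave 138 to 494. Regions as libraries moved the median of all identifiers by -0.18 (-0.13 with the filter on regions) and gave more lower calls (684, and 618 with the region block).

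For injury in CD45- segments (58), upper quartile factors gave 20, DESeq2 1, 50 CPM 19, regions as libraries 27 (14 with the filter on regions), voom 0 with either filter and single-segment identifiers left out 37. The young mutant section alone gave 26, the old mutant 12 and the wild type 6, and leave-one-out 18 to 164. In CD68+ segments (17), DESeq2 gave 3, no filter 52, regions as libraries 28 (17 with the filter on regions) and voom 0 (12 with the filter on regions, 3 higher and 9 lower). The young mutant section alone gave 27, the old mutant 5 and the wild type 11, and leave-one-out 1 to 33. In both segment types, counts of single sections and of regions as libraries take regions of the same animal as replicates. They allow no statement on animals. RTS0076055 lost its call in both segment types with voom. For the interaction (6), DESeq2 gave 0, 50 CPM 0, regions as libraries 1 (0 with the filter on regions), segments of at least 50000 counts 13 and single-segment identifiers left out 2, with 1 to 16 in leave-one-out. RTS0076055 lost that call in 21 of 31 alternatives, while its difference was 2.24 to 2.88 in leave-one-out. Counts at an unadjusted p under 0.05 were 65, 204 and 57 for the interaction values of 0, and 205 for voom in CD45- segments with the filter on regions.

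For ozone against air in CD45- segments (65), a prior count of 10 gave 23, no filter 347, 50 CPM 98, summed counts 138 and peri-injured regions alone 37, and leave-one-out 58 to 132. In CD68+ segments (27) the first 4 gave 13, 84, 62 and 63, injured regions alone 47, and leave-one-out 26 to 47. For mutant against wild type in CD45- segments (46), a prior count of 10 gave 29 and summed counts 105, and leave-one-out 46 to 59. In CD68+ segments (17) a prior count of 10 gave 7, no filter 53, 50 CPM 27 and summed counts 40, and leave-one-out 14 to 21. For old against young mutants these 4 gave 0, 16, 5 and 10 in CD45- segments (1), and 1, 15, 5 and 14 in CD68+ segments (3), with 1 to 4 and 2 to 6 in leave-one-out. No filter moved the median of all differences by 0.36 in CD45- and 0.30 in CD68+ segments for ozone against air, and in CD68+ segments by -0.31 for mutant against wild type and 0.19 for old against young mutants.

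The median difference between list and other identifiers was 0.166 for the macrophage-enriched and -0.223 for the non-immune list, with p = 0.279 and 0.116 for an estimated correlation and exact permutation p = 0.479 and 0.00207 (differences 0.0966 and -0.227). Tested against no change with fry, p was 0.0668 and 0.216. Lists of 100 or 400 were identical, since 59 identifiers met the rule. Leaving out sections gave 0.144 to 0.220 and -0.248 to -0.169. The CD68+ area difference was -61.4 with medians and -32.7 to 307 in leave-one-out, negative without the young mutant section. The CD45- area difference was 9885 with medians (exact permutation p = 0.0489) and 5106 to 10720 in leave-one-out. The area share gave -8.10 to -2.11.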

Other observations

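Some identifiers stood higher in the wild type ozone section than in the other sections. In CD68+ segments RTS0081477 averaged 2197 and 829 CPM in its injured and peri-injured regions and 56.8 CPM in air regions, and 81.3, 120, 83.3 and 70.0 CPM in the injured and peri-injured regions of the young and old mutant sections. RTS0066938 averaged 3774 and 3486 CPM there, 612 CPM in air regions, 1998 and 1156 CPM in the young mutant and 1030 and 644 CPM in the old mutant section. RTS0070870 in CD45- segments averaged 5468 and 6101 CPM in the wild type ozone section against 1333 CPM in air regions, 2483 and 1171 CPM in the young mutant and 2613 and 2320 CPM in the old mutant section. Each value comes from 1 animal.

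RTS0064055, which marked CD68+ segments, also differed between sections within them, at 2595 and 1103 CPM in injured and peri-injured wild type ozone regions, 640 and 506 CPM in young mutant, 436 and 236 CPM in old mutant and 283 CPM in air regions. Counts per 1000 area units in CD68+ segments were 5201 ± 1545 in air (SD, n = 4), 6007 ± 1456 in wild type ozone (SD, n = 8), 9300 ± 1509 in young mutant and 8506 ± 477 in old mutant regions (SD, n = 6).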
